A study of Mus musculus with 6 samples.

How the data were processed

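RNA was sequenced from natural killer (NK) cells, the cytotoxic innate lymphocytes, of the spleens of 8-week-old C57BL/6 mice. Control mice carried floxed Ezh2 alleles alone. In the second group, written Ezh2-deleted here, the floxed alleles were combined with a Cre recombinase knocked into Ncr1, the gene of the NK receptor NKp46, so that Ezh2 was deleted in cells that express NKp46. Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. Per the labels, the cells were sorted by flow cytometry as CD3-negative, CD19-negative, NKp46-positive and NK1.1-positive, the RNA was extracted with Trizol, and libraries were made with a NEBNext RNA kit and TruSeq indexes. Each group had 3 libraries, 6 in all. The labels did not say whether each library came from its own mouse, or whether mice were pooled, so every p-value measures only the spread between these libraries.

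The deposited matrix held raw counts per gene, which were whole numbers, for 21878 genes in the 6 libraries. The authors also deposited a file per library whose values were read as FPKM, fragments per kilobase of gene length, scaled to library depth. No header or label named that unit. It was inferred from the values, which were not whole and whose ratio to the counts depended on the gene. That ratio differed between libraries with an SD of 0.0313 on the log2 scale over 5772 genes with at least 500 counts. In each library, 14 to 20 genes had an FPKM of 0 and at least 10 counts. The submitters' processing notes listed Bowtie, without a version, and the genome builds mm8 and mm9. The role of each, the counting tool and the gene annotation were not given in the sources used here. Coordinates are not printed, because the build behind the counts was not known and the reference at hand was of another build. In the matrix, 27 gene symbols had been turned into dates by a spreadsheet program, and all 27 were restored from their NCBI GeneIDs. Of the 21878 genes, 21727 had a GeneID in the reference table and 97.8% were protein coding. Xist and the mitochondrially encoded genes were not in the matrix.

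Total counts were 17434388, 17083745 and 16029189 in control libraries 1 to 3, and 19681730, 17898147 and 16606909 in Ezh2-deleted libraries 1 to 3. Between 13606 and 13958 genes had a count in each library, and the top 10 genes took 5.13 to 5.71% of the counts. At these totals, 1 CPM (read count scaled to library size) stood for 16.0 to 19.7 counts, so values near 1 CPM carry a large counting error. The counts carried no molecular identifiers, so reads were not independent molecules. Pearson's correlation of log2 CPM across genes was 0.975 to 0.990 for the pairs of libraries; genes are not independent replicates. No pair of libraries in a group was a duplicate, as the chi-square of their counts per degree of freedom was 8.49 to 18.2.

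Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which kept 11411 genes and at least 99.9% of the counts. Library sizes were scaled by TMM, and the groups were compared by robust quasi-likelihood F-tests with 4 residual degrees of freedom. The biological coefficient of variation was 0.126. P-values were adjusted by the Benjamini-Hochberg method over the 11411 genes, with a threshold of 0.05. Adjusted p-values of genes are from edgeR unless another tool is named. Log2 fold changes are Ezh2-deleted minus control, fitted with a prior count of 0.125, and their standard error (SE) was taken as the absolute log2 fold change over the square root of F. Levels are TMM-normalised CPM, given as mean ± SD of 3 libraries per group.

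Before the data were examined, 31 gene lists were fixed, for NK biology, PRC2 and PRC1, cell cycle, metabolism, interferon response and markers of other cell types that a spleen or the sorting gate could hold. The 28 lists with at least 3 tested members were tested with camera of limma 3.58.1, which compares a list's genes with all other genes, at a preset inter-gene correlation of 0.01, and adjusted over the 28 lists. Camera with a correlation estimated for each list and fry, a rotation test of whether a list's genes move on balance in one direction, were alternatives. Fry also has a mixed form, which tests for changes in either direction. With an estimated correlation, camera tests each list at the residual degrees of freedom, 4 in the main fit. So few leave it little power to pass over 28 lists. For each list, members past the threshold were counted after adjustment over all tested genes, and also adjusted over the list alone. Named genes were chosen by a rule fixed before the data were examined. It took Ezh2; the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap, leaving out unnamed gene models; up to 4 members of each list with the smallest p; a panel of 15 NK genes; and Y-linked genes as a check of the sex of the mice. Genes named outside that rule are marked as chosen after their values were seen.

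Fixed in advance as other settings were DESeq2 size factors, upper-quartile factors and library size only in place of TMM; no filter and a stricter filter (5 CPM in at least 3 libraries); the Wald test of DESeq2 1.42.0; limma-voom; leaving out each of the 6 libraries in turn; the replicate number as a block; a minimum change of 2-fold; and limma on log2(FPKM + 1). Added after the data were seen were the level of Y-linked transcripts as a covariate, leaving out control 1 and Ezh2-deleted 3 together, camera with an estimated correlation within each of the other settings, and camera over the pathway names that the deposited matrix carried, for pathways of 10 to 300 tested genes. Exact permutation tests of single values were two-sided. With 3 libraries against 3 there are 10 splits, so such a test cannot give a p under 0.1. Differences between pairs of libraries matched by Y-linked level were taken on log2(CPM + 0.5). GC content and gene length were not tested as covariates.

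The procedure was tested on simulated data with 11411 genes, of which 200 were changed. It recovered 61.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 98.5% of those changed 4-fold, and 9.55% of its calls were false. A list of 40 genes shifted by 0.4 on the log2 scale was recovered, and 0 of 30 unshifted lists were called. The simulated genes were independent of one another, which the genes of a real list are not.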

Results

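Ezh2-deleted splenic NK cells were compared with control NK cells. Of 57 cell cycle genes tested, 20 fell in the Ezh2-deleted libraries, 0 rose and 37 did not pass (camera adjusted p = 6.7e-26 for the list; adjusted p = 0.50 with an estimated correlation). Among those that fell were Ube2c (log2 fold change −1.79), which encodes a ubiquitin-conjugating enzyme of mitotic exit, and the cyclin gene Ccnb2 (−1.39). Of 21 genes of immature NK cells, 5 fell, 1 rose and 15 did not pass (camera adjusted p = 3.8e-05; adjusted p = 0.50 with an estimated correlation), and the transcription factor gene Lef1 (−0.93) was among those that fell. Laptm4b, which encodes a lysosomal membrane protein, rose by 1.42 on the log2 scale. Transcripts of most cytotoxic effector molecules and of the terminal maturation marker Klrg1 (0.02 ± 0.21 SE, adjusted p = 0.98, n = 3 per group) did not pass the test.

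The targeted gene, Ezh2 (GeneID 14056), fell from 35.4 ± 2.58 CPM in the control libraries to 19.98 ± 2.13 CPM in the Ezh2-deleted libraries (mean ± SD, n = 3 per group), a log2 fold change of −0.82 ± 0.12 (SE) with an adjusted p of 0.00653. The level was 33.0, 38.1 and 35.0 CPM in control libraries 1 to 3, and 22.2, 17.99 and 19.7 CPM in Ezh2-deleted libraries 1 to 3. A floxed allele loses only part of its gene, and counts per gene do not show which exons the remaining reads came from.

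Across the 11411 tested genes, 381 passed the threshold, 135 higher and 246 lower in the Ezh2-deleted libraries, and 73 of them changed at least 2-fold. The groups did not overlap in CPM for any of the 381. They did not overlap for 2987 tested genes (26.2%). Chance gives 10% on average over the splits of the libraries. Genes are not independent, so a single split can lie well above 10% by chance, and the share in the other splits was not measured. With library size only in place of TMM, 143 genes were higher and 122 lower, so that 46.0% of calls were lower against 64.6% with TMM; in that setting 13 cell cycle genes, 3 immature NK genes and 1 glycolysis gene were lower, and Cd27 did not pass. The number of calls depended on single libraries: it was 90 without control 1, 35 without control 2, 475 without control 3, 60 without Ezh2-deleted 1, 201 without Ezh2-deleted 2 and 151 without Ezh2-deleted 3. Of the 58 named genes past the threshold, Ezh2, Laptm4b, Capg, Kif11, Gata6, Lef1, Ncr1, Ccr2, S1pr1 and Oas3, 10 in all, also passed with each of the 6 libraries left out in turn. The call ended for 46 of the 58 without control 2, 38 without Ezh2-deleted 1, 28 without control 1, 27 without Ezh2-deleted 3, 24 without Ezh2-deleted 2 and 10 without control 3, and no fold change turned.

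**Figure D1:**
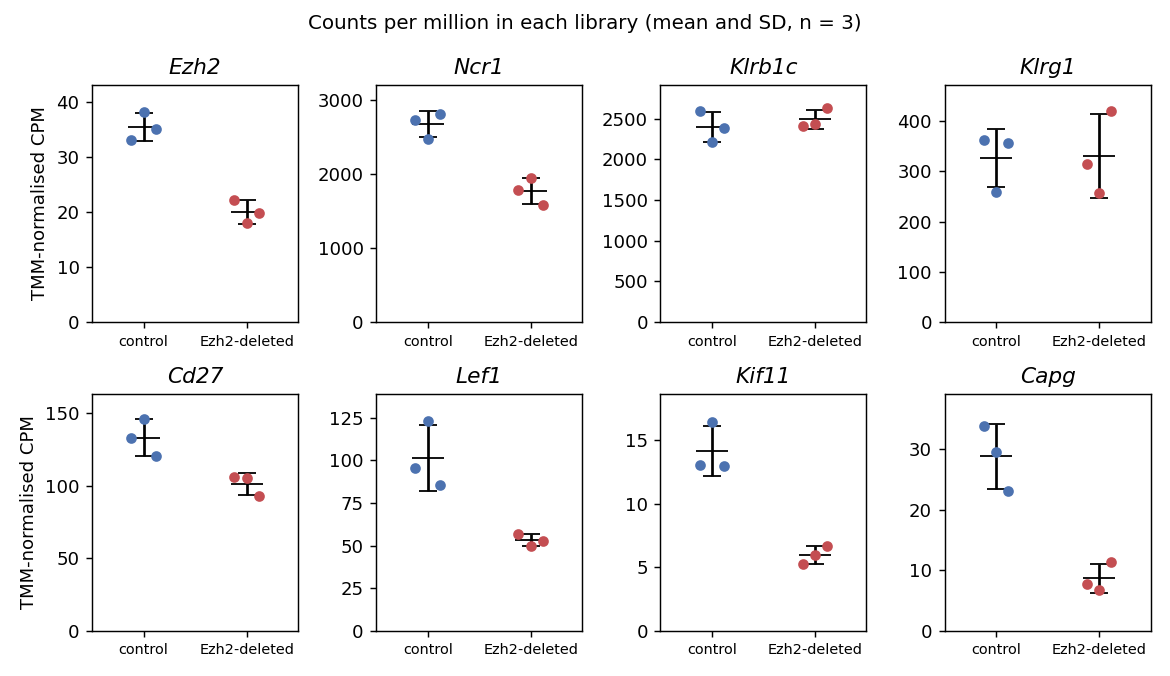
TMM-normalised CPM (vertical axis, from 0) of Ezh2, Ncr1, Klrb1c, Klrg1, Cd27, Lef1, Kif11 and Capg in each of the 3 control (blue) and 3 Ezh2-deleted (red) libraries; points are libraries, long bars the means and error bars the SD. The groups are apart for Ezh2, Ncr1, Cd27, Lef1, Kif11 and Capg and overlap for Klrb1c and Klrg1.

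Among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap, unnamed gene models left out, the 10 highest fold changes ranged from 1.09 to 1.72 on the log2 scale. Chl1, which encodes a cell adhesion molecule, rose from 2.95 ± 0.21 to 9.71 ± 4.34 CPM (adjusted p = 0.0237). Bmpr2, which encodes a receptor of bone morphogenetic proteins, rose from 4.91 ± 1.84 to 13.6 ± 0.85 CPM (adjusted p = 0.0111). Laptm4b rose from 3.24 ± 0.52 to 8.72 ± 0.95 CPM (adjusted p = 0.00677). The others were Spp1 (1.43), which encodes the secreted protein osteopontin, the homeodomain transcription factor genes Pbx1 (1.22) and Pbx3 (1.09), the protease inhibitor gene Serpine2 (1.19), Whamm (1.16), a regulator of actin assembly, the histone gene Hist1h2bc (1.10) and Bcl2a1d (1.09), of the anti-apoptotic A1 family. Laptm4b passed in each of the 6 settings with a library left out, and Bmpr2 did not pass without Ezh2-deleted 1. Serpine2, Whamm and Pbx3 did not pass without control 2 or Ezh2-deleted 1. Chl1 passed only without control 3 or Ezh2-deleted 2, Spp1 only without Ezh2-deleted 2, Pbx1 and Hist1h2bc only without control 3 or Ezh2-deleted 3, and Bcl2a1d only without control 1 or control 3. All of these were transcripts of low level, with means of at most 20.4 CPM in the Ezh2-deleted libraries.

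Of the 10 genes with the lowest fold changes under the same limits on level and overlap, 9 were in the cell cycle list, and the exception was Capg, which encodes an actin-capping protein. Capg fell from 28.8 ± 5.39 to 8.65 ± 2.44 CPM (log2 fold change −1.74 ± 0.20 SE, adjusted p = 0.0031). Of the 57 cell cycle genes, 20 were lower after adjustment over all tested genes and 33 when adjusted over the list alone. The list's median log2 fold change was −0.68, and camera placed it below all other genes (adjusted p = 6.7e-26; adjusted p = 0.50 with an estimated correlation). Kif11, which encodes a motor protein of the mitotic spindle, fell from 14.2 ± 1.96 to 5.96 ± 0.73 CPM (−1.25, adjusted p = 0.00594). Uhrf1, a factor for the maintenance of DNA methylation, fell from 16.2 ± 3.52 to 6.58 ± 0.76 CPM (−1.30, adjusted p = 0.00653). The genes of the mitotic regulators Ccnb1 (−1.23), Birc5 (−1.24) and Nusap1 (−1.31), of cyclin A2 (Ccna2, −1.29) and of the transcription factor E2f2 (−1.18) also fell. The 9 cell cycle genes among the 10 lowest were also of low level, with means of at most 16.6 CPM in the control libraries. Summed over the list, the level was 3326 ± 104 CPM in control and 2980 ± 127 CPM in Ezh2-deleted libraries. That is a smaller relative change than the median of the genes. The number of cell cycle genes called lower was 10 without control 1, 1 without control 2, 22 without control 3, 10 without Ezh2-deleted 1, 9 without Ezh2-deleted 2 and 13 without Ezh2-deleted 3. Kif11 and Capg passed in each of these settings, and Ube2c, Ccnb2, Uhrf1, Ccna2 and E2f2 in each but that without control 2. Nusap1 did not pass without control 2 or Ezh2-deleted 1, Ccnb1 without control 2, Ezh2-deleted 2 or Ezh2-deleted 3, and Birc5 passed only without control 3 or Ezh2-deleted 1. The median of the list lay between −0.79 and −0.63 in these 6 settings. Of the cyclin-dependent kinase inhibitors, which brake the cycle, 0 of 5 tested genes passed, and 0 when adjusted over the list alone (median 0.08; camera adjusted p = 0.39); Cdkn2d had a fold change of 0.25 (adjusted p = 0.12).

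**Figure D2:**
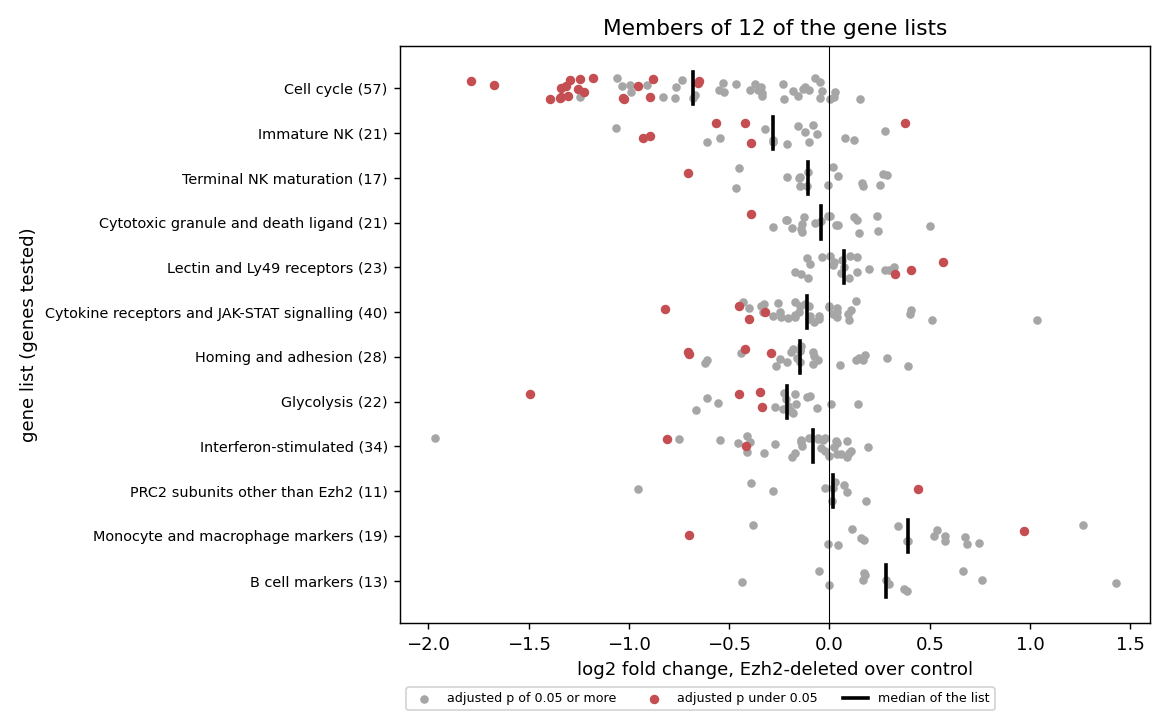
Log2 fold change, Ezh2-deleted over control (horizontal axis), of the tested members of 12 gene lists, with the number tested beside each name; red points had an adjusted p under 0.05 in edgeR, grey points did not, and black bars are medians. Cell cycle genes have the lowest median (−0.68) of the lists drawn.

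Of the 21 genes of immature NK cells, 5 fell and 1 rose (8 lower and 1 higher when adjusted over the list alone), with a median of −0.28, which lay between −0.30 and −0.17 with 1 library left out, the latter without Ezh2-deleted 3. The number that fell was 3 without control 1, 1 without control 2, 6 without control 3, 1 without Ezh2-deleted 1, 3 without Ezh2-deleted 2 and 3 without Ezh2-deleted 3. Lef1 fell from 101 ± 19.2 to 53.2 ± 3.59 CPM (adjusted p = 0.00528), and Gpr183, an oxysterol receptor that guides lymphocyte positioning, fell by 0.89 on the log2 scale. Sell, the homing receptor L-selectin, fell from 1830 ± 153 to 1367 ± 22.8 CPM (adjusted p = 0.0159). Cd27, a co-receptor of less mature NK cells, fell from 133 ± 12.6 to 101 ± 7.45 CPM (adjusted p = 0.0371), a call that held only without control 3 among the 6 settings with a library left out. Emb, which encodes the membrane protein embigin, also fell, and passed only without control 3. Gpr183 and Sell did not pass without control 2 or Ezh2-deleted 1. The gene that rose was Xcl1 (0.38 ± 0.08 SE, adjusted p = 0.0359), the chemokine that attracts cross-presenting dendritic cells. Among the settings with a library left out, it passed only without control 3 or Ezh2-deleted 2.

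Of the 17 genes of terminal NK maturation, 1 fell, 0 rose and 16 did not pass (2 lower and 1 higher when adjusted over the list alone; median −0.10; camera adjusted p = 0.39). Without Ezh2-deleted 3 the list passed camera (median −0.19, adjusted p = 0.021; adjusted p = 0.38 with an estimated correlation). The gene that fell was Lgals3 (−0.71 ± 0.14 SE, adjusted p = 0.0211), which encodes galectin-3; the call held only without control 3 or Ezh2-deleted 3 among the 6 settings with a library left out. S1pr5, a receptor for the exit of mature NK cells from tissue, had a fold change of 0.29 (adjusted p = 0.065), Prdm1 of −0.46 (adjusted p = 0.076) and Itgam, the integrin CD11b, of −0.21 (adjusted p = 0.18). Klrg1 was at 326.5 ± 58.4 CPM in control and 330.4 ± 83.1 CPM in Ezh2-deleted libraries.

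Of the 21 tested genes of cytotoxic granules and death ligands, 1 fell and 20 did not pass, with the same 1 when adjusted over the list alone (median −0.04, just above 0 with library size only; camera adjusted p = 0.40). Serpinb9, the granzyme B inhibitor, fell by 0.39 on the log2 scale (adjusted p = 0.039), a call that ended with any of the 6 libraries left out. Gzma was at 6498 ± 678 and 7654 ± 575 CPM (fold change 0.24, adjusted p = 0.15). Gzmb had a fold change of −0.21 (adjusted p = 0.25) and the perforin gene Prf1 of −0.13 (adjusted p = 0.43). Of the 20 cytokine and chemokine genes, Xcl1 rose, with the limit given above, and 19 did not pass, also when adjusted over the list alone (median 0.06; camera adjusted p = 0.81). Ifng had a fold change of −0.04 ± 0.34 SE (adjusted p = 0.96) and the activation marker Cd69 of −0.19 (adjusted p = 0.41).

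Receptor genes moved in both directions. Ncr1 (GeneID 17086), which carries the Cre insertion in the Ezh2-deleted mice, fell from 2671 ± 175 to 1769 ± 182 CPM (−0.59 ± 0.09 SE, adjusted p = 0.00653). Klrb1c, the gene of the other receptor used in the sort (NK1.1), was at 2398 ± 187 and 2492 ± 119 CPM (adjusted p = 0.73). Of the 23 lectin and Ly49 receptor genes, 3 rose, Klra9 (0.41), Klra5 (0.57) and Klre1 (0.33), 0 fell and 20 did not pass, with the same counts when adjusted over the list alone (median 0.07; camera adjusted p = 0.062). Without control 1 the list passed camera (adjusted p = 0.0061; adjusted p = 0.41 with an estimated correlation). With 1 library left out, 2 of these genes were higher without control 3, 1 without Ezh2-deleted 2 and 0 without any of the other libraries (control 1, control 2, Ezh2-deleted 1 and Ezh2-deleted 3). Ly49 genes are close paralogs, and how shared reads were assigned was not given in the sources used here. Klrk1, the gene of NKG2D, had a fold change of 0.07 (adjusted p = 0.60). Of the 31 other receptors and adaptors, Cd160 rose (0.37), Ncr1 and the adaptor gene Sh2d2a (−0.32) fell and 28 did not pass; adjusted over the list alone, 3 were higher and 4 lower (median −0.03, 0.01 with library size only; camera adjusted p = 0.32). With 1 library left out, Cd160 passed only without control 3 and Sh2d2a only without Ezh2-deleted 2.

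Of the 40 genes of cytokine receptors and JAK-STAT signalling, 4 fell, 0 rose and 36 did not pass, against 9 lower and 3 higher when adjusted over the list alone (median −0.11; camera adjusted p = 0.015; adjusted p = 0.56 with an estimated correlation). Il18rap, a subunit of the IL-18 receptor, fell from 1442 ± 56.7 to 1054 ± 73.0 CPM, and Ifngr1, of the interferon-gamma receptor, from 1620 ± 18.8 to 1228 ± 76.8 CPM. Socs2 (−0.82) and the type I interferon receptor gene Ifnar1 (−0.32) also fell. The number that fell was 2 without control 1, 0 without control 2, 5 without control 3, 1 without Ezh2-deleted 1, 3 without Ezh2-deleted 2 and 2 without Ezh2-deleted 3. Without control 3, 2 genes also rose and the camera adjusted p of this list was 0.056. Il2rb had a fold change of −0.24 (adjusted p = 0.096), and Il2ra, at 3.15 ± 1.46 CPM in control libraries, of −0.10 (adjusted p = 0.91).

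Of the 40 NK transcription factor genes, Lef1, Myb (−0.69) and Ets1 (−0.32) fell, 0 rose and 37 did not pass; 5 were lower and 1 higher when adjusted over the list alone (median −0.02, 0.02 with library size only; camera adjusted p = 0.32). Ets1, a factor for NK development, went from 1910 ± 148 to 1526 ± 92.8 CPM. With 1 library left out, Myb and Ets1 passed only without control 3 and Lef1 passed in each setting. The T-box factor genes Tbx21 (−0.01, adjusted p = 0.97) and Eomes (−0.10, adjusted p = 0.47) did not pass. Of the 19 genes of innate lymphoid cells type 1 (ILC1) and tissue residency, Socs2 fell (with 1 library left out, only without control 3 or Ezh2-deleted 2) and 18 did not pass; adjusted over the list alone, 2 were lower and 1 higher (median −0.14; camera adjusted p = 0.33).

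Of the 28 homing and adhesion genes, 4 fell, 0 rose and 24 did not pass; 6 were lower and 1 higher when adjusted over the list alone (median −0.15; camera adjusted p = 0.0020; adjusted p = 0.56 with an estimated correlation). The chemokine receptor gene Ccr2 fell from 945.9 ± 82.8 to 581 ± 64.8 CPM (−0.70, adjusted p = 0.00458). S1pr1, the receptor for exit from lymphoid tissue along sphingosine-1-phosphate, fell from 210.3 ± 24.4 to 129 ± 15.8 CPM (−0.71, adjusted p = 0.00677). Sell and S1pr4 (−0.29) fell as well; Sell did not pass without control 2 or Ezh2-deleted 1, and S1pr4 did not pass with any of the 6 libraries left out. Of the 22 glycolysis genes, 4 fell, 0 rose and 18 did not pass, with 8 lower when adjusted over the list alone (median −0.21; camera adjusted p = 2.7e-06; adjusted p = 0.56 with an estimated correlation). They were the glucose transporter genes Slc2a3 (−0.45) and Slc2a1 (−0.35), Ldha (−0.34), which encodes lactate dehydrogenase A, and Aldoc (−1.49), an aldolase gene at 3.25 ± 0.92 CPM in control libraries. The number that fell was 1 without control 1, 1 without control 2, 2 without control 3, 0 without Ezh2-deleted 1, 1 without Ezh2-deleted 2 and 1 without Ezh2-deleted 3, and Aldoc, Ldha and Slc2a1 did not pass in any of these 6 settings.

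Of the 34 interferon-stimulated genes, 2 fell, 0 rose and 32 did not pass, with 5 lower when adjusted over the list alone (median −0.08; camera adjusted p = 0.016; adjusted p = 0.78 with an estimated correlation). Oas3, an antiviral oligoadenylate synthetase gene, fell from 44.6 ± 2.54 to 25.5 ± 2.29 CPM (−0.81, adjusted p = 0.00421), and Ifit2 fell by 0.42 on the log2 scale, a call that held only without control 3 or Ezh2-deleted 2 among the 6 settings with a library left out. The camera adjusted p of this list was 0.099 without control 1 and 0.19 without Ezh2-deleted 2. Of the 77 ribosomal protein genes, Rpl18a (−0.38) and Rps5 (−0.37) fell, 0 rose and 75 did not pass, also when adjusted over the list alone (median −0.10; camera adjusted p = 0.00072; adjusted p = 0.78 with an estimated correlation). Both genes passed only without control 3 among the 6 settings, and the camera adjusted p was 0.12 without control 1 and 0.20 without Ezh2-deleted 2. Of the 76 oxidative phosphorylation genes, 0 passed, also when adjusted over the list alone (median 0.05; camera adjusted p = 0.062). Without control 1 or Ezh2-deleted 2 this list passed upward (adjusted p = 0.0022 and 0.00012; adjusted p = 0.79 and 0.77 with an estimated correlation).

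Of 11 other PRC2 subunit genes, Suz12, a core subunit, rose from 33.2 ± 1.17 to 45.1 ± 5.03 CPM (0.44 ± 0.11 SE, adjusted p = 0.040), a call that held only without Ezh2-deleted 3 among the 6 settings with a library left out. Of the others 0 rose or fell, and adjusted over the list alone 1 was higher and 1 lower (median 0.02, mean −0.07; camera adjusted p = 0.94). Of 20 genes of Polycomb repressive complex 1 (PRC1), Cbx4 (−0.59) and Cbx6 (−0.53) fell, 0 rose and 18 did not pass; adjusted over the list alone, 3 were higher and 2 lower (median 0.07; camera adjusted p = 0.84). Cbx4 did not pass without control 2, and Cbx6 passed only without control 3 among these settings. Homeobox and developmental regulators, classical PRC2 targets, were mostly below the filter: 4 of 100 were tested. Gata6 fell from 2.04 ± 0.56 to 0.23 ± 0.12 CPM (−3.07 ± 0.51 SE, adjusted p = 0.0111), which rests on 2 to 7 counts per Ezh2-deleted library. Gata6 was not called by the Wald test of DESeq2, which gave it no adjusted p. It also did not pass without control 1 and Ezh2-deleted 3 together. Hoxb3 had a fold change of 1.28 (adjusted p = 0.11) and Hoxb4 of 0.79 (adjusted p = 0.18), and adjusted over the list alone 2 were higher and 1 lower. The list's median was 0.34, its mean −0.28, and camera gave a downward direction (adjusted p = 0.82), so these measures differ in sign. The filter was rerun in each setting, so the members of this list could change along with the libraries. The median was −0.36 without Ezh2-deleted 2, −0.10 without control 2 and −0.09 with no filter. It was 0.0054 without Ezh2-deleted 1, 0.02 without Ezh2-deleted 3, 0.26 without control 1 and 0.40 without control 3. With 1 library left out, Hoxb3, Hoxb4 and Meis1 were never below 1.04, 0.52 and −0.36. The median of the 4 genes named as tested therefore stayed positive, and the negative medians came from changed members.

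Of 23 apoptosis and survival genes, Bcl2a1d rose and 22 did not pass, also when adjusted over the list alone. Bcl2a1b, of the same A1 family, had a fold change of 0.60 and did not pass, also with any of the 6 libraries left out. How reads shared within this family were assigned was not given in the sources used here. The median of the list was −0.01 (0.03 with library size only), the mean 0.05 and the camera adjusted p 0.90. Of 33 immediate early and heat shock genes, Dusp5, a phosphatase gene of MAP kinase feedback, fell by 0.40 on the log2 scale (adjusted p = 0.0156) and 32 did not pass, also when adjusted over the list alone. Dusp5 did not pass without control 2 or Ezh2-deleted 1, and without Ezh2-deleted 3 another 3 genes of the list were higher, Hspa8 and Hsp90ab1 among them. The median of that list was −0.02 (0.02 with library size only), the mean 0.06 and the camera adjusted p 0.81, and the sign of the median depended on single libraries, from −0.23 without Ezh2-deleted 1 to 0.25 without Ezh2-deleted 3 (adjusted p = 0.80 and 0.86 with an estimated correlation). The heat shock gene Hspa8 was at 1131 ± 57.5 and 1799 ± 509 CPM (0.67, adjusted p = 0.13).

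Markers of other cell types were measured as well. Of the 13 B cell marker genes 0 passed (median 0.28; camera adjusted p = 0.14) and of the 8 dendritic cell markers 0 passed (median 0.14; camera adjusted p = 0.48), also when adjusted over the list alone. Without Ezh2-deleted 1 the B cell list passed camera (median 0.46, adjusted p = 0.0073; adjusted p = 0.64 with an estimated correlation). Of the 7 T cell markers 0 passed, also when adjusted over the list alone (median −0.21; camera adjusted p = 0.82), and Cd3e was at 2.26 ± 0.60 and 1.39 ± 0.59 CPM. Of the 4 plasma cell markers, Jchain rose from 1.85 ± 0.65 to 4.45 ± 0.42 CPM (adjusted p = 0.044), also when adjusted over the list alone (median 0.47; camera adjusted p = 0.10); the call ended with any of the 6 libraries left out. Of the 19 monocyte and macrophage markers, Hmox1, which encodes a heme-degrading enzyme, rose from 34.8 ± 3.45 to 68.1 ± 15.6 CPM (adjusted p = 0.0134), Ccr2 fell and 17 did not pass, also when adjusted over the list alone (median 0.39; camera adjusted p = 0.048; adjusted p = 0.78 with an estimated correlation). Hmox1 did not pass without control 2 or Ezh2-deleted 2, and without Ezh2-deleted 1 the number of markers called higher was 3. Of the 9 megakaryocyte and platelet markers 0 passed and 1 was higher when adjusted over the list alone (median 0.71; camera adjusted p = 0.038; adjusted p = 0.78 with an estimated correlation). The camera call of the macrophage list ended without control 2, control 3, Ezh2-deleted 2 or Ezh2-deleted 3 (adjusted p = 0.14, 0.26, 0.20 and 0.47). That of the megakaryocyte list ended without control 1, control 3 or Ezh2-deleted 2 (adjusted p = 0.22, 0.11 and 0.20). Both calls also ended with library size only (adjusted p = 0.075).

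Single libraries stood apart from the rest. Hemoglobin transcripts summed to 2745 CPM in control 1, against 188 to 549 CPM in the other libraries. The 11 erythroid marker genes had a median of −1.42 (0 passed, 1 lower when adjusted over the list alone; camera adjusted p = 0.11), which was 0.74 without control 1, −1.80 without control 2 and −1.92 without control 3, each past the threshold at the preset correlation. With an estimated correlation the adjusted p was 0.41, 0.72 and 0.85 in these 3 settings. MHC class II transcripts summed to 292 CPM in Ezh2-deleted 3, against 138 to 165 CPM in the others. The summed level of 4 Y-linked genes, Ddx3y, Uty, Kdm5d and Eif2s3y, was 5.46, 429 and 144 CPM in control libraries 1 to 3 and 169.5, 437 and 2.84 CPM in Ezh2-deleted libraries 1 to 3. Libraries with almost no Y-linked transcripts, with a high level and with a level between these were thus found once in each group. The levels between, 144 CPM in control 3 and 169.5 CPM in Ezh2-deleted 1, argue against a single mouse as the source of either library. Without control 1 and Ezh2-deleted 3 together, a choice made after the data were seen, 57 genes passed, 26 higher and 31 lower, of which 45 were among the 381, and 7 cell cycle genes and 1 immature NK gene were lower. With the Y-linked level as a covariate, also chosen after the data were seen, 287 genes passed, 106 higher and 181 lower, and 264 of them were among the 381.

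**Figure D3:**
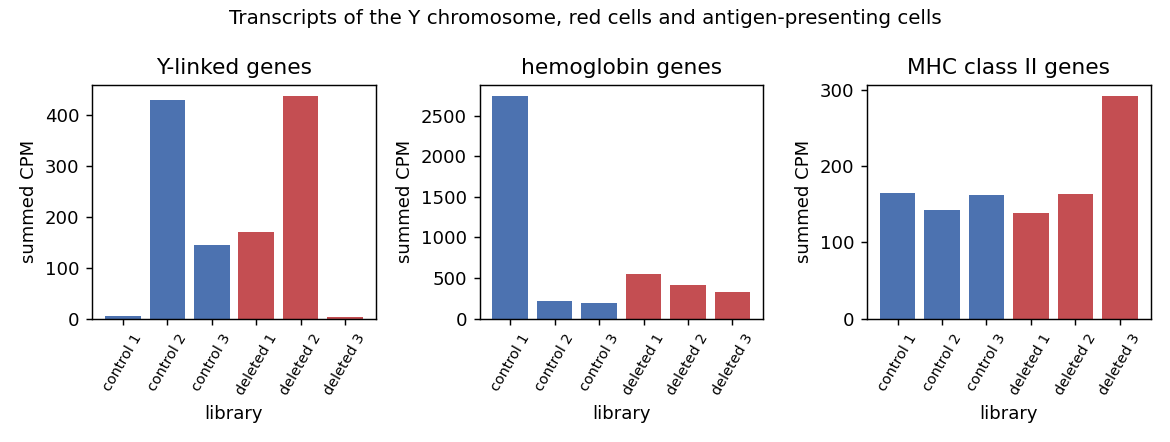
Summed CPM (vertical axes, from 0) of Y-linked, hemoglobin and MHC class II genes in each of the 6 libraries, control in blue and Ezh2-deleted in red; each bar is 1 library. Control 1 has 2745 CPM of hemoglobin transcripts and Ezh2-deleted 3 has 292 CPM of MHC class II transcripts, and each group holds 1 library with almost no Y-linked transcripts.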

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

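The Y-linked covariate, the setting without control 1 and Ezh2-deleted 3, and the estimated correlation within other settings were chosen after the data were seen; the other alternatives were planned. Ezh2 was lower in every setting tried, and missed the threshold in 3: with the replicate block (−0.82), where the fit has fewer degrees of freedom, with the 2-fold minimum (−0.82), which it does not reach, and in limma on log2(FPKM + 1) (−0.88, adjusted p = 0.053). The counts of genes higher and lower (135 and 246 with TMM in edgeR) were 297 and 411 without the filter, 344 and 462 by DESeq2, 82 and 141 by limma-voom, 30 and 43 with the 2-fold minimum, and 26 and 31 without control 1 and Ezh2-deleted 3. With library size only, 122 were lower. In limma on log2(FPKM + 1), 0 were higher and 0 lower, while 2120 genes had an unadjusted p under 0.05, against 2411 in edgeR. With 1 library left out, the counts ranged from 5 to 219 higher and from 30 to 256 lower. The causes were not tested.

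The deviations of same-numbered libraries from their group means correlated at −0.15, 0.07 and −0.08. They thus gave no sign that the replicate number pairs the libraries. With 3 libraries per group they cannot exclude that same-numbered libraries were handled together. With the number as a block, 3 genes were higher and 14 lower.

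Without control 1 and Ezh2-deleted 3, terminal NK maturation had a median of −0.12 (camera adjusted p = 0.015; adjusted p = 0.53 with an estimated correlation). With 1 library left out it lay between −0.19 and 0.0020. For immature NK genes the median was −0.28, with an adjusted p of 0.50 by camera with an estimated correlation and 0.092 by fry. For cell cycle genes it was −0.68 (adjusted p = 0.50 and 0.070). These calls were thus made only at the preset correlation. The estimated correlation also comes with few degrees of freedom, so their loss cannot be laid to the correlation alone. A setting gave 2 lists that had not passed a call in the opposite direction. Immediate early and heat shock genes ranged from −0.23 to 0.25 with 1 library left out, and erythroid markers from −1.92 to 0.74, and the latter were at 0.92 without control 1 and Ezh2-deleted 3. With an estimated correlation, 0 lists passed in any of these settings, and the lowest adjusted p was 0.33. The few residual degrees of freedom left these tests little power, so this does not show that the lists were unchanged. In the main fit 0 of 28 lists passed by fry, and 19 passed by its mixed form. That form does not compare a list with other genes. Over the other lists and settings, 308 results stayed on their side of the threshold, 32 lost their call and 23 gained one. Over the 143 named genes, Ezh2 left out, and all settings, 2070 results stayed, 415 lost and 37 gained a call. Of the called values 0 reversed, and 57 values that were not past the threshold changed sign. Depth limits the precision of genes near 1 CPM, such as Gata6 and Aldoc.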

Other observations

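The settings with each of the 6 libraries left out in turn, that without control 1 among them, were fixed in advance. So were the main fit and the counts of list members past the threshold. The other tests in this part were chosen after the results were seen, as were the genes and pathways of the next paragraph.

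Single genes of lipid synthesis were among those that fell in the Ezh2-deleted libraries. Scd2, a stearoyl-CoA desaturase gene, had the smallest adjusted p of all genes (0.000615) and fell from 246 ± 13.2 to 135 ± 9.25 CPM (log2 fold change −0.86 ± 0.08 SE, n = 3 per group). Fasn, the fatty acid synthase gene, fell from 242 ± 31.3 to 141 ± 10.2 CPM (adjusted p = 0.0031), and Acaca (−0.61) and Acsl4 (−0.43) fell too. Scd2 and Fasn passed in each of the 6 settings with a library left out, and Acaca and Acsl4 only without control 3 or Ezh2-deleted 2. Scd1 (−0.37, adjusted p = 0.66), Srebf1 (−0.34, adjusted p = 0.094) and Elovl6 (adjusted p = 0.996) did not pass. Flna, which encodes the actin cross-linker filamin A, fell by 0.57 on the log2 scale (adjusted p = 0.00677), and Myh9 (−0.51), Vcl (−0.56), Tln1 (−0.48), Vasp (−0.42) and Actb (−0.52) fell too. Of these, Flna passed in each of the same settings, Myh9 and Vcl in 5 of the 6, Vasp in 4, and Tln1 and Actb in 3. At low levels, Penk, which encodes enkephalin precursor, rose from 0.30 ± 0.12 to 1.89 ± 0.78 CPM (adjusted p = 0.0192) and the protein S gene Pros1 from 1.88 ± 0.40 to 6.33 ± 1.02 CPM (adjusted p = 0.00677). Penk did not pass without control 1, control 2 or Ezh2-deleted 2, and Pros1 did not pass without control 2. Among 290 pathways tested with camera, 1 passed, arachidonic acid metabolism, which was higher (median 0.40, 26 genes, adjusted p = 0.012; adjusted p = 0.98 with an estimated correlation; adjusted p = 0.086 without control 1 and Ezh2-deleted 3), with 0 of its genes past the threshold on their own. Fatty acid biosynthesis had 3 of 11 genes called lower and did not pass (adjusted p = 0.11). Regulation of the actin cytoskeleton had 9 of 139 genes called lower and 2 higher, with a median of −0.01, and did not pass (adjusted p = 0.62). These genes are therefore given one by one, and no change of either pathway is claimed.

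Of 57 cell cycle genes, 20 fell in the Ezh2-deleted libraries and 37 did not pass. Without control 1, the library with erythroid transcripts, the median of the list was −0.67 (quartiles −1.02 and −0.27), which argues against dividing erythroid cells in that library as the cause. Between libraries of the 2 groups matched by the rank of their Y-linked level, it was −0.60, −0.38 and −0.79. The mean was −0.59 ± 0.21 (SD, 3 pairs). Such a mean mostly repeats the group difference whichever libraries are paired, so it does not test the sex of the mice. The Y-linked level was 1.08, 31.9 and 97.9% of the highest in the controls of these pairs. It was 0.587, 37.3 and 97.1% in their Ezh2-deleted partners. This balance between the groups argues against sex as the cause. The real split of the libraries gave the median farthest from 0, 0.68 against 0.44 for the highest of the others. It was 1 of 10 splits, too few for a share under 0.05. By camera at the preset correlation, the unadjusted p of the list was 2.4e-27 in the real split. The splits that mixed the genotypes gave 3.2e-17 to 0.61, so very small p-values of this test also arose there. Each of these splits held unequal numbers of control libraries in its groups, so part of any genotype difference remained. Their p-values are therefore no reference without that difference. Cell stages were not separated, so a smaller share of dividing, less mature cells in the Ezh2-deleted libraries stays open. Less cycling within each stage stays open as well. So does an effect of Cre or of its insertion in Ncr1, since 0 libraries had Cre without the floxed alleles. Chance also stays open, given the few splits.

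For the number of genes called, the real split gave 381 and the highest other 2 (1 of 10 splits as large). In a mixed split, part of any genotype difference lies within the groups and widens their spread. Few calls there were thus likely if genes differ by genotype. For the number of lists called by camera at the preset correlation, the real split gave 9 and the highest other 12, and 5 of the 10 splits gave as many. In both cases 10 splits are too few for a share under 0.05. The other splits mixed the genotypes unequally, so part of any genotype difference also stayed between their groups.

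Ncr1 was lower in the Ezh2-deleted libraries. The median log2 fold change of 8 other NK genes (Klrb1c, Klrk1, Klrd1, Nkg7, Gzma, Prf1, Tbx21 and Eomes) was 0.0247 (quartiles −0.08 and 0.10), which argues against a smaller share of NK cells as the cause. The Cre recombinase lies in the Ncr1 gene in this group alone, and 0 libraries had Cre without the floxed alleles. An effect of the insertion on Ncr1 and an effect of Ezh2 loss therefore cannot be told apart. For every other gene and list, an effect of Cre or of the insertion likewise cannot be told apart from that of Ezh2 loss.

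Hmox1 and Spp1, which macrophages of the spleen express strongly, were higher in the Ezh2-deleted libraries. Hmox1 did not pass without control 2 or Ezh2-deleted 2, and among the 6 settings with a library left out Spp1 passed only without Ezh2-deleted 2. The 12 other macrophage markers of the list with at least 5 CPM, leaving out Ccr2, which the homing list also holds, differed by 0.28 on the log2 scale (exact permutation p = 0.4). Relative to them, Hmox1 was higher by 0.67, with groups that did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). Hmox1 was looked at because it had passed in these same libraries, so it was likely to lie above the other markers. The value therefore does not decide whether more macrophage RNA was the cause. A change of Hmox1 within macrophages stays open too. Spp1 was higher by 1.05 on average relative to these markers, but the groups overlapped (exact permutation p = 0.2), so macrophage RNA and a change in NK cells cannot be told apart for Spp1. C1qa, one of the abundant macrophage genes, was at 8.87 ± 2.01 and 13.3 ± 2.84 CPM, and the sorting gate for NKp46 and NK1.1 should remove macrophages.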
